A study of Mus musculus with 21 samples.

How the data were processed

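Expression was measured on 21 oligonucleotide arrays of 45101 probe sets each, from mouse nephron progenitors sorted by Six2-driven GFP at E16.5. Per the labels' protocols each sample held 40000 cells, the medium held 10% serum, BIO was given at 4 µM against the same volume of DMSO, and RNA went through 2 rounds of amplification before labelling with biotin. There were 3 arrays in each of 7 groups: fresh cells, dispersed cells after 24 h in DMSO or BIO, aggregates after 24 h in DMSO or BIO, and aggregates after BIO for 24 h followed by DMSO or BIO for another 24 h. A group of aggregates after 48 h in DMSO alone was not part of the labels, so effects of the second day carry time in culture.

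The deposited values were linear signal intensities between 0.1 and 18025. The software and the scaling that made them are not given in the sources used here. The plan written before the data were examined had assumed log2 values, and it named log2(value + 1) with quantile normalization for linear values whose distributions differ between arrays. The deposited medians differed (6.46 to 6.74 on the log2 scale), so quantile normalization was used and the deposited scaling became an alternative. At most 0.288% of probe sets held the same value on any pair of arrays.

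Probe sets were named through the probe table and brought to current symbols with RefSeq names, 34741 through the reference and 204 with the name in the table. Of all probe sets 34945 had one symbol, 932 had several, 9160 had none and 64 were controls, and only those with one symbol were tested. Each gene was represented by its probe set with the highest mean over all arrays, which left 18193 genes. Among named genes, other probe sets of the same gene passed in the same direction in 224 of 402 results and in the opposite direction in 3, Prrx1 and Tyms for aggregation with BIO and Podxl for culture as aggregates.

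Background was the 95th percentile of 27 bacterial control probe sets, a signal of 41.9. Where the mean of one group lay below it, each array below background was raised to it before the group means were taken, and the text gives their difference as at least so many fold, and where both groups lay below, no fold is given. Interaction values keep the log2 scale and can rest on groups below background.

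Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 21 arrays (14 residual and 1.625 prior degrees of freedom) and moderated t tests. P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. The 10 comparisons and 24 gene lists from textbook knowledge were chosen before the data were examined. Lists were tested with limma camera at the preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison, and members were also counted when adjusted over the list alone. Some listed genes are not reported here. Some genes sit in more than one list, 6 of the pretubular genes and 5 of the Notch pathway genes among them.

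Named genes are the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap, for BIO in aggregates, BIO in dispersed cells, BIO removal and culture as aggregates, and the 5 and 5 largest for the other comparisons, without provisional symbols. The condition on overlap was not asked of the interaction. Axin2, Lef1, Wnt4, Lhx1, Six2 and Cited1 were added for the BIO comparisons, and up to 4 genes of each list described, or the 1 largest where none passed.

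The fit was tested on simulated data with the gene means and residual spreads of these arrays. Changes were planted for BIO in aggregates, only in genes above the median level. Of 50 genes each, 50% of those changed by log2 0.5 were recovered, 94% of those changed by 1, 98% of those changed by 2 and 96% of those changed by -1, with 5 unchanged genes among 174 calls. A comparison simulated without change gave 0 calls. Genes were simulated as independent, without effects that genes of an array share, so these figures hold only for that case. The 3 arrays in each group limit the precision, and 76.0 to 79.6% of genes lay above background on each array.

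Alternatives planned before the data were examined were the deposited scaling, centring on the median, a filter on dim genes, and the mean of all probe sets or every probe set. Also planned were only the arrays compared, array weights, a variance trend with a robust prior, the replicate number as a block, a 2-fold minimum, log2(value + 16) and leaving out each array. Chosen after the data were examined were leaving out 4 arrays apart from their groups in the 3' beta-actin control, and the Gapdh 3' over 5' ratio or the 3' beta-actin control signal as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.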

Results

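Nephron progenitors carrying a Six2-driven GFP were sorted from E16.5 mouse kidneys and profiled on 21 arrays, 3 for each of 7 conditions. Freshly sorted cells were set beside cells kept dispersed for 24 h in DMSO or in BIO, and beside cells pelleted into aggregates for 24 h in DMSO or BIO. BIO was present for all 24 h of this culture. Rises and falls with BIO at 24 h are therefore differences from DMSO and not changes from fresh cells. BIO inhibits the kinase GSK3 and so stabilises beta-catenin, which carries the canonical Wnt signal. A further pair of conditions followed aggregates through a second day, after BIO for the first 24 h, with DMSO or with more BIO. The labels call the arrays biological replicates and do not say whether separate litters, sorts or cultures stand behind them, so the p-values measure only the spread between these arrays, which may be technical. Changes are log2 fold changes ± SE of the limma fit with n = 3 arrays per group, and p-values are adjusted over 18193 genes unless stated otherwise.

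Median signals were 87.2 to 106, and 76.0 to 79.6% of genes lay above background on each array. Each array correlated with the others of its group at a mean r of 0.976 to 0.992 over the genes above the median level, and the first 3 principal components carried 44.3, 20.3 and 10.8% of the variance. Some array properties followed the conditions. Median signals were 93.3 ± 4.1 and 90.7 ± 3.1 (SD, n = 3) in aggregates after 24 h in DMSO and BIO, below every fresh or dispersed array, with group means of 103.6 to 104.1. The Gapdh 3' over 5' ratio was 14.2 ± 0.99 and 13.4 ± 1.9 in these aggregates, 12.1 ± 0.46 and 9.79 ± 0.60 in dispersed cells in DMSO and BIO, 9.50 ± 0.90 in fresh cells, 10.8 ± 1.4 after BIO and then DMSO, and 8.14 ± 1.7 after 48 h of BIO. The 3' beta-actin control probe set had a mean signal of 3706 ± 1487 (SD, n = 3) in aggregates given BIO for 24 h, against 10560 ± 2547 in aggregates in DMSO, 8929 ± 296 in dispersed cells with BIO and 12100 ± 179 in dispersed cells in DMSO. Fresh cells had 10040 ± 1790, aggregates after BIO and then DMSO 12330 ± 456, and aggregates after 48 h of BIO 8301 ± 2614. Counts with this control or the Gapdh ratio as a covariate, choices made after the data were examined, are therefore given beside the comparisons they moved. The aggregated BIO arrays at 24 h read 2669 to 5410 in the beta-actin control and every other array at least 6344. For comparisons with that group the covariate is thus largely tied to the group itself. All dispersed BIO arrays also lay below all dispersed DMSO arrays in this control. A call lost with the covariate can come from a wider SE as well as from a smaller change.

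For every gene named below as one of the largest rises or falls of a comparison, all 3 arrays of one group lay above all 3 of the other, an ordering that chance alone gives in 10% of comparisons of 3 with 3. Across the 10 comparisons and 24 gene lists, 83 of 240 list results passed at a preset correlation between genes and 45 of these held with an estimated correlation. List p-values below are those with the estimated correlation, adjusted within a comparison. The median, the mean and the direction of the test differed in sign in 48 list results, of which 0 had passed.

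**Figure D1:**
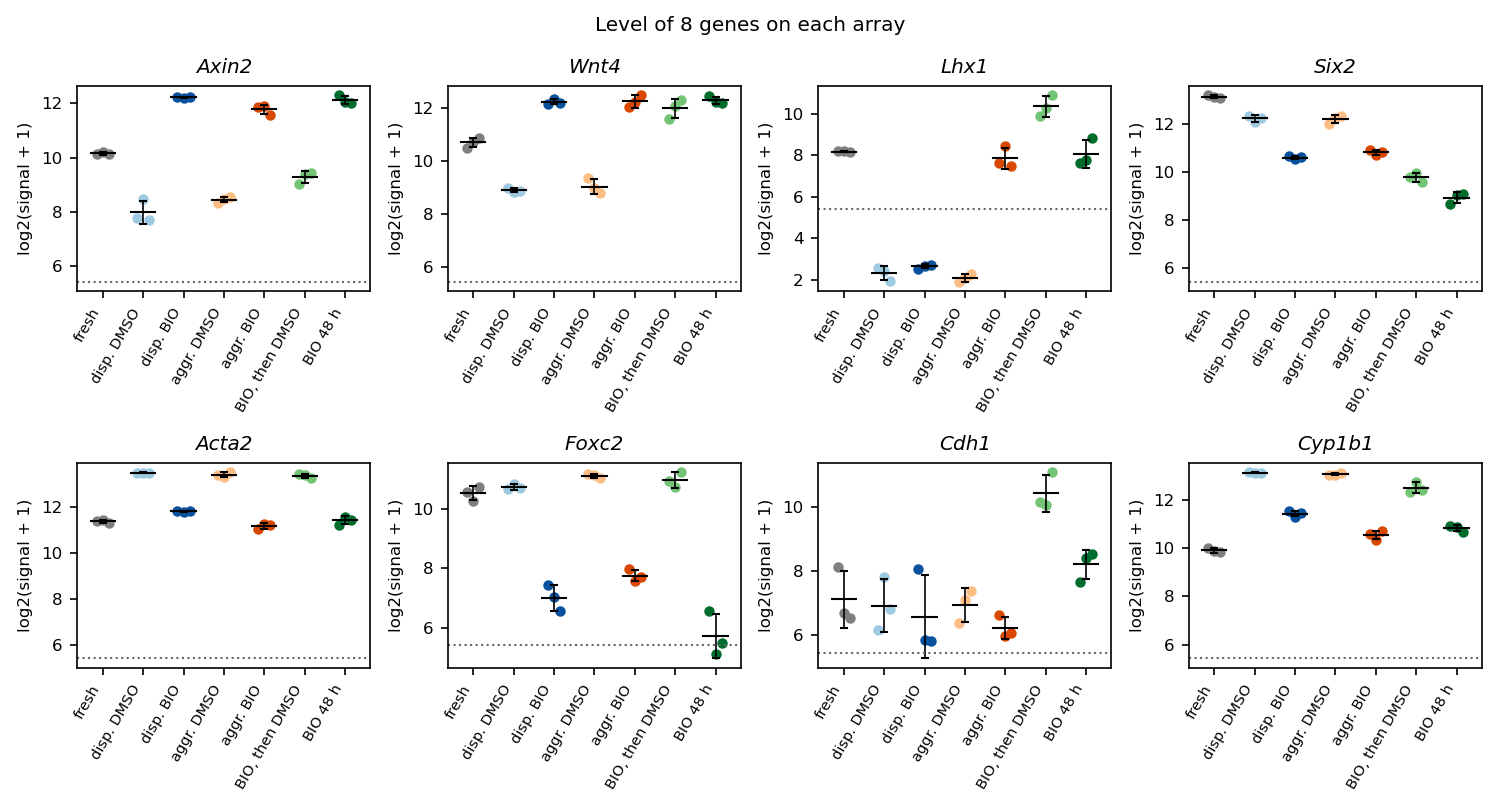
Log2 signal of Axin2, Wnt4, Lhx1, Six2, Acta2, Foxc2, Cdh1 and Cyp1b1 on each array of the 7 conditions.

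In aggregates, genes of the Wnt/beta-catenin pathway and of the pretubular aggregate were higher after 24 h of BIO than in DMSO. The pretubular aggregate is the first structure that forms when progenitors are induced to make nephrons. In DMSO culture as aggregates 12 of 18 pretubular genes and 11 of 19 Wnt targets fell from the fresh level. The BIO groups were not set against fresh cells, so a rise past that level was not tested. Genes of contraction, stroma, mesenchyme and the immediate early response fell. Six2, the transcription factor that keeps progenitors undifferentiated, fell as well. Of 18193 genes, 5455 changed, 3185 higher and 2270 lower, and 1950 of them changed at least 2-fold (888 higher, 1062 lower). Without quantile normalization 2433 were higher and 2729 lower. With the 3' beta-actin control as a covariate 2405 changed (947 higher, 1458 lower), 2033 of them shared.

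Svopl, a transporter-like gene, reached a signal of 1233 from below background in DMSO and so rose at least 28.8-fold (adjusted p = 1.83e-12). Sp5, a transcription factor that answers directly to beta-catenin, rose at least 43.6-fold (adjusted p = 1.72e-08), and Wif1, a secreted Wnt inhibitor, at least 5.84-fold (adjusted p = 3.19e-08). The procollagen enhancer gene Pcolce2 rose at least 16.3-fold (adjusted p = 1.24e-07), the POU factor Pou3f1 at least 25.02-fold (adjusted p = 4.11e-06), Jakmip1 at least 9.07-fold (adjusted p = 1.82e-06). Egfl6, which encodes a secreted matrix protein, was above background in both groups and rose by 5.21 ± 0.16 (adjusted p = 3.44e-12).

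Feedback genes of the pathway rose together. Tnfrsf19 gained 5.06 ± 0.17 (adjusted p = 5.05e-12), Notum, whose product strips Wnt ligands of their lipid, 4.98 ± 0.19 (adjusted p = 2.02e-11), Lef1 3.47 ± 0.17 (adjusted p = 3.79e-10) and Axin2 3.32 ± 0.17 (adjusted p = 4.47e-10). Of the 19 canonical Wnt targets measured, 13 rose and 0 fell, 13 rising when adjusted over the list alone (list adjusted p = 0.000273).

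Wnt4, the ligand that drives progenitors through the transition to epithelium, rose by 3.23 ± 0.18 (adjusted p = 1.07e-09). Lhx1, a homeobox gene of the renal vesicle, was below background in DMSO and at a signal of 230 with BIO, at least 5.38-fold higher (adjusted p = 1.21e-09). That signal was no higher than in fresh cells. The chemokine receptor gene Cxcr4 rose by 5.07 ± 0.71 (adjusted p = 4.09e-05), and Fgf8 changed with both groups below background (adjusted p = 0.00329). Of 18 pretubular aggregate and renal vesicle genes 13 rose and 1 fell, 16 and 1 when adjusted over the list alone (list adjusted p = 0.00782).

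Progenitor genes split. Six2 fell by 1.38 ± 0.12 (adjusted p = 3.37e-07) and Cited1, a marker of the least advanced progenitors, was below background in both groups (adjusted p = 0.00665). Osr1 fell at least 8.94-fold (adjusted p = 0.000175) and Meox1 at least 8.97-fold (adjusted p = 7.41e-06), ending below background. Uncx rose by 2.22 ± 0.17 (adjusted p = 3.85e-08) and Gdnf, the ligand that calls the ureteric bud, by 2.12 ± 0.39 (adjusted p = 0.000483). Over 18 nephron progenitor genes 8 rose and 6 fell, the same when adjusted over the list alone, and the median of 0.43 and the mean of -0.01 had opposite signs (list adjusted p = 0.739).

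Among the deepest falls, Ms4a2, which encodes a chain of the IgE receptor, was at least 118-fold below its signal of 5072 in DMSO (adjusted p = 7.55e-09). The tight junction gene Cldn1 fell at least 55.2-fold (adjusted p = 2.82e-09), Pgm5 at least 39.7-fold (adjusted p = 1.21e-06) and Inhba, the activin A subunit, at least 26.6-fold (adjusted p = 3.48e-10). Ms4a2 and Inhba were also below background in fresh cells and came up in DMSO culture, a rise that was absent with BIO. Mgam fell at least 13.9-fold (adjusted p = 3.62e-08) and Ldlrad4 at least 10.8-fold (adjusted p = 9.76e-05). Ptgs2, the inducible cyclooxygenase, fell by 5.76 ± 0.28 (adjusted p = 2.61e-10).

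Contractile genes went down without exception. Tagln fell by 5.70 ± 0.31 (adjusted p = 1.03e-09) and Myl9 by 4.03 ± 0.20 (adjusted p = 4.02e-10), while Cnn1 fell at least 2.70-fold (adjusted p = 1.21e-09) and Ankrd1 at least 9.96-fold (adjusted p = 1.16e-07), and all 15 serum response and contractile genes fell, 15 also when adjusted over the list alone (list adjusted p = 0.000721). In the stroma, Pdgfrb fell by 2.50 ± 0.24 (adjusted p = 8.5e-07), Foxd1, the factor of stromal progenitors, by 2.31 ± 0.15 (adjusted p = 6.15e-09), Col1a1 by 2.04 ± 0.22 (adjusted p = 2.98e-06) and Col3a1 by 2.02 ± 0.10 (adjusted p = 4.02e-10). Of 14 interstitial stroma genes 10 fell and 2 rose, the same when adjusted over the list alone (list adjusted p = 0.00377). The mesenchymal regulators Snai2 and Zeb2 fell by 2.29 ± 0.15 (adjusted p = 6.37e-09) and 2.14 ± 0.24 (adjusted p = 3.78e-06), Fn1 by 2.19 ± 0.10 (adjusted p = 2.56e-10). Here 8 of 12 mesenchymal genes fell and 1 rose, 10 and 1 when adjusted over the list alone (list adjusted p = 0.00144).

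Podocyte genes were lower, with Foxc2 down by 3.37 ± 0.29 (adjusted p = 1.93e-07), Synpo by 3.17 ± 0.36 (adjusted p = 4.49e-06) and Clic5 by 3.34 ± 0.60 (adjusted p = 0.000404). Of 8 genes in the list 4 fell and 1 rose, 5 and 1 when adjusted over the list alone (list adjusted p = 0.0245). Of 13 immediate early genes 11 fell and 0 rose, 11 when adjusted over the list alone (list adjusted p = 0.0139), led by Ier3 at -3.14 ± 0.26 (adjusted p = 1.3e-07) and Egr3 at -2.87 ± 0.31 (adjusted p = 2.5e-06). The Notch effector genes Heyl and Hey1 rose by 2.64 ± 0.30 (adjusted p = 3.83e-06) and 2.19 ± 0.22 (adjusted p = 9.14e-07) and Lfng fell by 1.45 ± 0.16 (adjusted p = 2.66e-06). Of 12 Notch pathway genes 4 rose and 3 fell, the same when adjusted over the list alone (list adjusted p = 0.879). Bmp7 rose by 2.41 ± 0.13 (adjusted p = 1.21e-09) and Bmp4 fell by 1.61 ± 0.17 (adjusted p = 2.52e-06).

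Cell cycle genes rose in number and little in size, 13 of 21 rising and 0 falling (15 and 1 when adjusted over the list alone), with Plk1 at 1.21 ± 0.19 (adjusted p = 0.000102) and Tyms at 1.16 ± 0.18 (adjusted p = 0.000121). The list passed at the preset correlation and not with an estimated correlation (adjusted p = 0.186), and glycolysis and hypoxia genes likewise, 1 rising and 4 falling of 15, 2 and 5 when adjusted over the list alone (adjusted p = 0.164 with an estimated correlation). Ndrg1 in that list fell by 2.12 ± 0.22 (adjusted p = 1.74e-06). With the 3' beta-actin control as a covariate the changes of Osr1, Gdnf, Cxcr4, Clic5, Cited1, Plk1, Tyms and Fgf8 no longer passed, and of the cell cycle genes 0 rose, at a median of 0.33 against 0.47. Falls with it numbered 2 of 8 podocyte, 7 of 14 stromal, 7 of 12 mesenchymal and 8 of 13 immediate early genes, while the medians went from -0.92 to -0.48, -1.31 to -1.67, -1.17 to -1.06 and -0.96 to -1.20.

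Genes of other cell types moved little. Proximal tubule genes rose 0 and fell 1 of 9, loop of Henle and distal tubule genes 2 and 0 of 10, ureteric bud and collecting duct genes 3 and 1 of 13, endothelial genes 2 and 0 of 11, leukocyte and macrophage genes 1 and 1 of 12, erythroid genes 0 and 0 of 7, and epithelial junction and keratin genes 1 and 0 of 16. When adjusted over the list alone the proximal tubule list had 0 of either and the others were unchanged. Wfdc2, of the distal nephron, rose by 3.11 ± 0.28 (adjusted p = 2.85e-07) and Krt19 fell by 2.27 ± 0.27 (adjusted p = 7.67e-06). Sterol synthesis genes rose 1 and fell 2 of 14, p53 targets 1 and 1 of 10, interferon genes 0 and 0 of 8, aryl hydrocarbon receptor targets 1 and 1 of 7, FGF and MAPK feedback genes 3 and 4 of 11, and BMP and TGF-beta feedback genes 2 and 4 of 11. When adjusted over the list alone p53 targets had 0 of either and FGF and MAPK genes 4 and 5. List adjusted p values ran from 0.164 for BMP and TGF-beta feedback to 0.999.

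**Figure D2:**
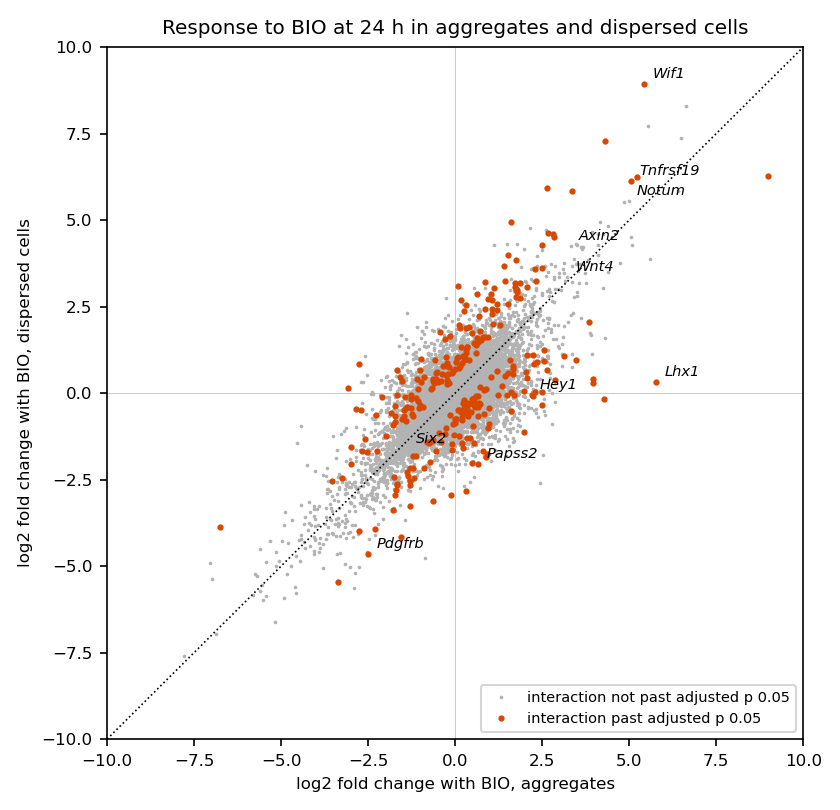
Change of each gene with BIO in aggregates against its change with BIO in dispersed cells.

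Cells kept dispersed also raised Wnt targets with BIO, and fewer of the pretubular genes. Contractile, stromal, mesenchymal and podocyte genes fell here too. Of 18193 genes, 5230 changed, 2792 higher and 2438 lower, 1898 at least 2-fold (771 higher, 1127 lower). Without quantile normalization 2252 were higher and 2699 lower, and with each array centred on its median 2138 and 2658. Of the genes that rose, 2017 rose in both formats (488.8 expected if calls were independent), and 1684 fell in both (304.2 expected), against 13 and 11 that went opposite ways. Calls are not fully independent, since all comparisons share the residual spread of each gene, so this expectation can be too low. The changes in aggregates and in dispersed cells, which share no arrays, correlated over all genes at r = 0.738 and at 0.895 over the 9096 brighter genes (Spearman 0.604 over all).

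Wif1 rose at least 36.4-fold (adjusted p = 9.3e-11), Sp5 at least 46.3-fold (adjusted p = 1.06e-09), Jakmip1 at least 40.4-fold (adjusted p = 3.48e-08) and Fgf20, a ligand that keeps progenitors alive, at least 20.96-fold (adjusted p = 1.25e-10). Egfl6 rose at least 66.4-fold (adjusted p = 6.41e-13), Svopl at least 5.51-fold (adjusted p = 4.35e-11), the adhesion gene Tenm2 at least 25.4-fold (adjusted p = 9.88e-08), and Tnfrsf19 by 6.13 ± 0.17 (adjusted p = 6.41e-13). Notum gained 5.54 ± 0.19 (adjusted p = 4.01e-12), Axin2 4.25 ± 0.17 (adjusted p = 3.01e-11) and Lef1 3.74 ± 0.17 (adjusted p = 1.25e-10). Of 19 Wnt targets 13 rose and 0 fell, 14 when adjusted over the list alone (list adjusted p = 2.65e-05).

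Wnt4 rose by 3.36 ± 0.18 (adjusted p = 5.55e-10), Cxcr4 by 4.28 ± 0.71 (adjusted p = 0.000213) and the cadherin gene Cdh4 by 2.74 ± 0.13 (adjusted p = 1.67e-10). Lhx1 stayed below background in both groups, with no passing change (adjusted p = 0.519). Of 18 pretubular genes 6 rose and 2 fell, 8 and 2 when adjusted over the list alone (list adjusted p = 0.377). Six2 fell by 1.62 ± 0.12 (adjusted p = 4.28e-08), Meox1 by 2.33 ± 0.40 (adjusted p = 0.000265) and Osr1 by 2.25 ± 0.66 (adjusted p = 0.0161, lost with the beta-actin covariate), while Spock2 rose by 2.95 ± 0.31 (adjusted p = 1.91e-06). Cited1 was below background in both groups (adjusted p = 0.00569). The progenitor list rose 5 and fell 5 of 18, 6 and 6 when adjusted over the list alone (list adjusted p = 0.83).

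Ms4a2 fell at least 111-fold (adjusted p = 8.37e-09), with the anion transporter gene Slc26a7 at least 68.8-fold (adjusted p = 2.03e-10), Pgm5 at least 41.3-fold (adjusted p = 9.17e-07), the potassium channel gene Kcnn4 at least 17.3-fold (adjusted p = 4.9e-11), Ldlrad4 at least 10.7-fold (adjusted p = 9.44e-05) and Brinp1 at least 8.89-fold (adjusted p = 3.33e-06). Nxph1 fell by 5.98 ± 0.26 (adjusted p = 6.13e-11) and Hpgd, which breaks down prostaglandins, by 5.85 ± 0.22 (adjusted p = 1.22e-11). Tagln fell by 5.28 ± 0.31 (adjusted p = 2.01e-09) and Myl9 by 3.64 ± 0.20 (adjusted p = 1.05e-09), and again all 15 contractile genes fell, 15 when adjusted over the list alone (list adjusted p = 0.00133). Pdgfrb lost 4.66 ± 0.24 (adjusted p = 5.27e-10), Smoc2 3.33 ± 0.28 (adjusted p = 1.26e-07) and Foxd1 2.35 ± 0.15 (adjusted p = 4.16e-09). Of 14 stromal genes 8 fell and 2 rose, 9 and 2 when adjusted over the list alone (list adjusted p = 0.0122).

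Of 12 mesenchymal genes 7 fell and 0 rose, 8 when adjusted over the list alone (list adjusted p = 0.00814), Zeb2 by 2.50 ± 0.24 (adjusted p = 5.92e-07) and Fn1 by 2.22 ± 0.10 (adjusted p = 1.56e-10). Of 8 podocyte genes 4 fell and 0 rose, 5 when adjusted over the list alone (list adjusted p = 0.0268), Foxc2 by 3.74 ± 0.29 (adjusted p = 4.93e-08). Of 13 immediate early genes 12 fell and 0 rose, 12 when adjusted over the list alone (list adjusted p = 0.0119), Egr2 by 2.46 ± 0.18 (adjusted p = 1.93e-08) and Dusp1 by 2.03 ± 0.20 (adjusted p = 7.37e-07). Hes1, a Notch effector, fell by 2.18 ± 0.18 (adjusted p = 1.26e-07). Spry1 fell by 1.81 ± 0.10 (adjusted p = 6e-10) and Dusp6 by 1.76 ± 0.11 (adjusted p = 2.5e-09), both brakes on FGF signalling, with 6 of 11 FGF and MAPK feedback genes falling and 1 rising, the same when adjusted over the list alone (adjusted p = 0.377 with an estimated correlation, the preset one having passed).

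Interferon genes and the cell cycle list also passed at the preset correlation alone. Of 8 interferon genes 4 fell and 0 rose, 5 when adjusted over the list alone (adjusted p = 0.377 with an estimated correlation), Oasl2 at least 2.78-fold (adjusted p = 0.0107). Dispersed DMSO replicate 3 stood apart in these genes, with Ifit1 at 10.3 against 6.79 and 6.67 on the other arrays of its group, and without it 0 fell. Of 21 cell cycle genes 14 rose and 0 fell, 15 when adjusted over the list alone (adjusted p = 0.217 with an estimated correlation), Mcm3 by 0.74 ± 0.10 (adjusted p = 2.11e-05). Cyp1b1 fell by 1.71 ± 0.12 (adjusted p = 9.73e-09), and Irx3, of the distal nephron, rose by 2.42 ± 0.21 (adjusted p = 1.54e-07).

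Whether aggregation altered the answer to BIO was tested as an interaction, the change in aggregates minus the change in dispersed cells. Pretubular genes gained more in aggregates, and several direct Wnt targets gained more in dispersed cells. The interaction covered 285 of 18193 genes, 132 higher and 153 lower, 163 of them at least 2-fold (74 higher, 89 lower). With the 3' beta-actin control as a covariate 120 passed (30 higher, 90 lower), 97 of them shared. Leaving out 1 array gave 171 genes without aggregated BIO replicate 1, 177 without dispersed DMSO replicate 3 and 180 without dispersed BIO replicate 3.

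Lhx1 had an interaction of 5.44 ± 0.45 (adjusted p = 1.12e-05), above background in aggregates with BIO alone among the 4 groups. Its antisense neighbour Lhx1os (adjusted p = 0.000457) and the phospholipase gene Plcd4 (adjusted p = 0.000536) were likewise above background only there, and Morn5 was below it throughout (adjusted p = 0.0064). The laminin gene Lama4 stood at 3.58 ± 0.59 (adjusted p = 0.00502). Papss2, which makes the donor for sulfation, gained 2.72 ± 0.41 (adjusted p = 0.00223), Hey1 2.26 ± 0.30 (adjusted p = 0.001) and Heyl 1.98 ± 0.42 (adjusted p = 0.024). Of 18 pretubular genes 6 were higher and 2 lower in the interaction, 11 and 2 when adjusted over the list alone (list adjusted p = 0.0426). With the beta-actin covariate Lama4, Morn5, Papss2 and Heyl no longer passed, and 4 pretubular genes were higher.

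Wif1 had an interaction of -3.49 ± 0.56 (adjusted p = 0.00404), Dact1 of -1.54 ± 0.15 (adjusted p = 6.03e-05), Apcdd1 of -1.29 ± 0.27 (adjusted p = 0.0239) and Tnfrsf19 of -1.07 ± 0.23 (adjusted p = 0.0283). Among 19 Wnt targets 5 were lower and 0 higher, 6 when adjusted over the list alone (list adjusted p = 0.000389). Axin2 stood at -0.93 ± 0.24 (adjusted p = 0.069), Lef1 at -0.27 ± 0.24 (adjusted p = 0.737), Wnt4 at -0.13 ± 0.25 (adjusted p = 0.891), Six2 at 0.25 ± 0.18 (adjusted p = 0.636) and Cited1, below background throughout, had an adjusted p = 0.989. Serpina9 was below background throughout (adjusted p = 0.0149). The netrin receptor gene Dcc at -3.34 ± 0.58 (adjusted p = 0.00611), Tenm2 at -3.30 ± 0.69 (adjusted p = 0.0221) and Lrrc20 at -3.21 ± 0.64 (adjusted p = 0.0161) were the other large negative values. Wif1, Dcc, Tenm2 and Lrrc20 were each below background in some of the 4 groups, so these sizes rest partly on values below it.

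The integrin gene Itga8, a progenitor gene, was 1.74 ± 0.16 higher (adjusted p = 4.26e-05), Uncx 1.13 ± 0.23 (adjusted p = 0.0207), Pdgfrb 2.16 ± 0.34 (adjusted p = 0.00385) and Hes1 1.27 ± 0.26 (adjusted p = 0.0183), while Irx3 was 1.58 ± 0.29 lower (adjusted p = 0.01) and Prrx1 1.36 ± 0.21 lower (adjusted p = 0.00243). Notch pathway genes were higher in 3 of 12, 6 when adjusted over the list alone (adjusted p = 0.215 with an estimated correlation). FGF and MAPK feedback genes were higher in 2 of 11, 5 when adjusted over the list alone (adjusted p = 0.215 with an estimated correlation), with Spry2 at 0.99 ± 0.23 (adjusted p = 0.0439). Contractile genes were lower in 2 of 15, Ccn2 at -0.82 ± 0.16 (adjusted p = 0.014), 2 when adjusted over the list alone (adjusted p = 0.301 with an estimated correlation). Sterol synthesis and interferon lists, which passed at the preset correlation, had 0 genes past the threshold (adjusted p = 0.147 and 0.524 with an estimated correlation). With the beta-actin covariate 3 Wnt targets were still lower and 1 Notch pathway gene higher, against 0 stromal, 0 FGF and MAPK feedback and 0 contractile genes. The medians of the Wnt, Notch, FGF and MAPK and contractile lists went from -0.56 to -0.55, 0.45 to 0.19, 0.52 to 0.25 and -0.28 to -0.31. Uncx, Pdgfrb, Hes1, Spry2, Ccn2, Apcdd1, Serpina9, Tenm2 and Lrrc20 no longer passed with it.

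Aggregation by itself did little. In DMSO, aggregates differed from dispersed cells in 477 of 18193 genes, 334 higher and 143 lower, of which 109 differed at least 2-fold (61 higher, 48 lower), and 0 of 24 gene lists passed. Without quantile normalization 106 were higher and 166 lower, and with each array centred on its median 796 and 126, so the direction of the set as a whole rests on the scaling. Leaving out dispersed DMSO replicate 1, 2 or 3 gave 164, 249 or 138 genes, and leaving out aggregated DMSO replicate 1, 2 or 3 gave 164, 306 or 215. With only the arrays of these groups 6 genes passed, 4 of them shared, and with array weights or only the brighter genes 829 or 859 did. Of the genes named next, only Blvrb passed among those 6. With the Gapdh ratio as a covariate 226 differed.

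Crym, a progenitor gene that encodes a thyroid hormone binding protein, was 1.06 ± 0.15 higher in aggregates (adjusted p = 0.00242), and Ptpro, a phosphatase gene of podocytes, 1.48 ± 0.32 higher (adjusted p = 0.0255). Among the largest rises, Mad1l1 was at least 3.29-fold higher (adjusted p = 0.041) and Blvrb at least 1.87-fold (adjusted p = 0.00564), while Slc51b (adjusted p = 0.0222), Dlx3 (adjusted p = 0.0149) and Neurod6 (adjusted p = 0.0425) were below background in both groups. Mss51 was 2.33 ± 0.27 lower (adjusted p = 0.000737), the integrin gene Itga5 at least 4.03-fold lower (adjusted p = 0.00874), Map3k8 at least 2.18-fold (adjusted p = 0.0356), AA386476 at least 2.00-fold (adjusted p = 0.00564) and Myl6b at least 1.36-fold (adjusted p = 0.0329). Id4 was 0.58 ± 0.11 lower (adjusted p = 0.0101), Ier2 0.53 ± 0.11 higher (adjusted p = 0.0196). The stromal gene Meis1 was 0.45 ± 0.09 higher (adjusted p = 0.0149) and the sterol gene Mvd 0.59 ± 0.13 (adjusted p = 0.0268), both lost without quantile normalization.

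In BIO, aggregation lowered several Wnt feedback genes. Pretubular, Notch pathway and FGF feedback lists had more rises than falls but did not hold with an estimated correlation. Aggregates with BIO differed from dispersed cells with BIO in 3135 of 18193 genes, 2289 higher and 846 lower, 636 at least 2-fold (383 higher, 253 lower). Without quantile normalization 999 were higher and 1060 lower, the median over all genes moving by -0.13, and with each array centred on its median 3277 and 594. With the 3' beta-actin control as a covariate 358 differed (163 higher, 195 lower), 297 of them shared, and with the Gapdh ratio 1087 (667 higher, 420 lower). Without dispersed BIO replicate 1, dispersed BIO replicate 2 or aggregated BIO replicate 2 there were 2046, 1907 or 1908.

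Lhx1 rose at least 5.38-fold (adjusted p = 2.76e-07), Plcd4 at least 6.60-fold (adjusted p = 4.93e-06), Pnliprp2 at least 1.74-fold (adjusted p = 3.7e-05), the caspase gene Casp4 at least 1.78-fold (adjusted p = 0.0259) and Ms4a6d at least 1.63-fold (adjusted p = 0.0018). Heyl was 2.61 ± 0.30 higher (adjusted p = 5.52e-05), Papss2 2.40 ± 0.29 (adjusted p = 8.19e-05), Hey1 2.18 ± 0.22 (adjusted p = 1.7e-05) and Hes1 1.30 ± 0.18 (adjusted p = 0.000296). Pretubular genes were higher in 10 of 18 and lower in 2, 11 and 2 when adjusted over the list alone (adjusted p = 0.196 with an estimated correlation). Notch pathway genes were higher in 5 of 12 and lower in 0, 6 when adjusted over the list alone (adjusted p = 0.28 with an estimated correlation). Itga8 was 1.74 ± 0.12 higher (adjusted p = 4.69e-07), Uncx 1.39 ± 0.17 higher (adjusted p = 8.01e-05).

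Wif1 was 2.64 ± 0.40 lower in aggregates (adjusted p = 0.000502), Apcdd1 1.35 ± 0.19 (adjusted p = 0.000345), Dact1 1.26 ± 0.11 (adjusted p = 4.54e-06) and Nkd1 0.80 ± 0.13 (adjusted p = 0.00112). Of 19 Wnt targets 5 were lower and 0 higher, 5 when adjusted over the list alone, and this list held (list adjusted p = 0.00294). Etv4 was 1.03 ± 0.20 higher (adjusted p = 0.00319), though the mean of its probe sets was lower, and Spry2 0.76 ± 0.17 higher (adjusted p = 0.00578), with 6 of 11 FGF and MAPK feedback genes higher, 8 when adjusted over the list alone (adjusted p = 0.28 with an estimated correlation). Pdgfrb was 1.92 ± 0.24 higher (adjusted p = 0.000137). Ccn2 was 0.99 ± 0.11 lower (adjusted p = 5.74e-05), in a contractile list with 3 lower and 1 higher of 15, 5 and 1 when adjusted over the list alone (adjusted p = 0.196 with an estimated correlation). Prrx1 was 1.51 ± 0.15 lower (adjusted p = 1.44e-05) with another of its probe sets higher, and mesenchymal genes were lower in 6 of 12 and higher in 1, 6 and 4 when adjusted over the list alone (adjusted p = 0.196 with an estimated correlation). Sterol synthesis genes were lower in 2 of 14, 2 when adjusted over the list alone (adjusted p = 0.25 with an estimated correlation).

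The 5 largest falls by log2 estimate under BIO had another property in common. Malat1, a nuclear noncoding RNA, was 5.01 ± 0.95 lower in aggregates (adjusted p = 0.0024) and the splicing gene Srrm2 3.72 ± 0.67 (adjusted p = 0.00179), while Gdap10 was at least 9.62-fold lower (adjusted p = 0.00122), Nfix at least 3.44-fold (adjusted p = 0.0103) and Taok3 at least 3.34-fold (adjusted p = 0.0037). On single arrays the deviations of these genes from their group means followed the 3' beta-actin control at r = 0.927 (permutation p = 0.00069, n = 21 arrays). This control was chosen after the data were examined, and the p-value does not allow for that choice. With that control as a covariate the median change of Malat1, Gdap10, Srrm2, Nfix and Taok3 went from -3.72 to -0.15 and 0 of them passed. With it Lhx1, Plcd4, Pnliprp2, Itga8, Uncx, Wif1, Apcdd1, Dact1, Heyl, Hey1, Ccn2 and Prrx1 still passed, while Casp4, Ms4a6d, Papss2, Hes1, Nkd1, Etv4, Spry2 and Pdgfrb did not. The rises numbered 5 of 18 pretubular, 2 of 12 Notch pathway, 0 of 11 FGF and MAPK feedback and 0 of 14 stromal genes, and 3 of 19 Wnt targets fell. The medians of these lists went from 0.81 to 0.59, 0.48 to 0.18, 0.50 to 0.22, 0.18 to 0.16 and -0.32 to -0.45.

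**Figure D3:**
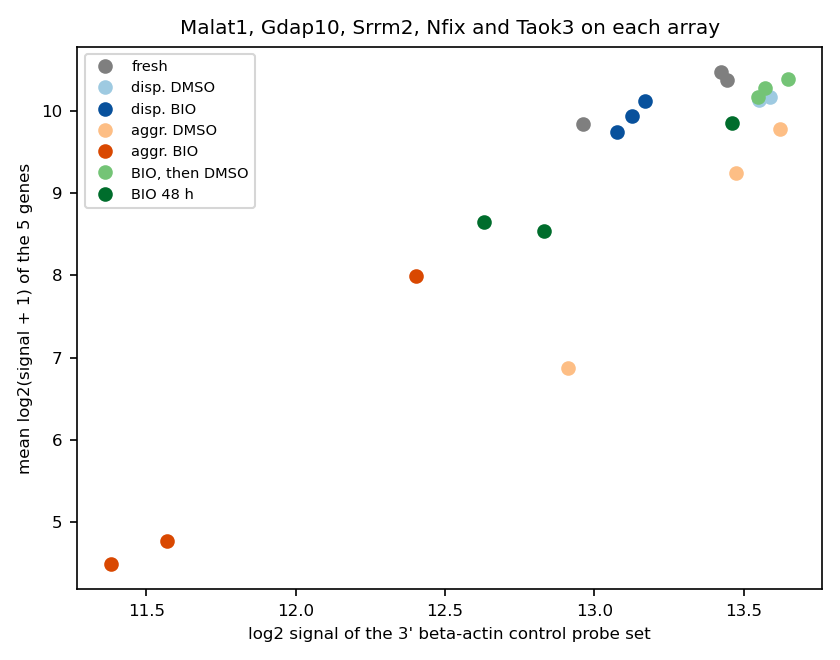
Mean level of Malat1, Gdap10, Srrm2, Nfix and Taok3 on each array against the 3' beta-actin control signal.

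When BIO was taken away for the second day, the Wnt feedback genes fell, and contractile, stromal and podocyte genes came up. Lhx1 and several Notch pathway genes were higher without BIO on this day than with it. Rises and falls on removal are differences between these groups at 48 h, and can come from a change with BIO kept on. Aggregates after BIO and then DMSO differed from those kept in BIO for 48 h in 3711 of 18193 genes, 1690 higher and 2021 lower, 1452 at least 2-fold (723 higher, 729 lower). Without quantile normalization 1873 were higher and 1629 lower, and with only the arrays of these groups 1820 differed. Of the genes that BIO had raised in aggregates at 24 h, 878 of 3185 were lower after removal (353.8 expected if calls were independent). Among those it had lowered, 788 of 2270 were higher (210.9 expected). Changes in the same direction numbered 298 and 179 (295.9 and 252.2 expected).

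Wif1 fell at least 111-fold on removal (adjusted p = 2.54e-09), with Jakmip1 at least 51.7-fold (adjusted p = 2.59e-07), Sptlc3, of sphingolipid synthesis, at least 33.7-fold (adjusted p = 2.81e-07) and Dcc at least 31.4-fold (adjusted p = 6.09e-08). Tnfrsf11b fell at least 9.60-fold (adjusted p = 3.54e-06) and Fgf20 at least 5.34-fold (adjusted p = 1.48e-08). Prss56 was at least 22.4-fold lower than with BIO kept (adjusted p = 4.61e-06) and Krt33a at least 9.87-fold (adjusted p = 9.07e-07). Prss56 and Krt33a were below background after 24 h of BIO and came up with BIO kept on, so their differences lay in that rise. Sp5 fell by 5.16 ± 0.46 (adjusted p = 5.05e-07), Notum by 5.00 ± 0.19 (adjusted p = 2.71e-11), Axin2 by 2.83 ± 0.17 (adjusted p = 5.55e-09) and Lef1 by 1.44 ± 0.17 (adjusted p = 1.25e-05). Of 19 Wnt targets 12 fell and 1 rose, 13 and 1 when adjusted over the list alone (list adjusted p = 0.000263).

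Wnt4 stood at -0.31 ± 0.18 (adjusted p = 0.256). Lhx1 was 2.28 ± 0.32 higher after removal (adjusted p = 5.97e-05), at a signal of 1298 against 267 with BIO kept. The cadherin gene Cdh6 rose by 3.06 ± 0.11 (adjusted p = 2.71e-11) and the Notch ligand gene Dll1 by 1.81 ± 0.23 (adjusted p = 2.4e-05), while Cxcr4 fell at least 14.0-fold (adjusted p = 5.57e-05). Of 18 pretubular genes 6 rose and 3 fell, 6 and 4 when adjusted over the list alone (list adjusted p = 0.311). Notch1 rose by 1.15 ± 0.12 (adjusted p = 3.6e-06), Nrarp by 1.88 ± 0.34 (adjusted p = 0.000702) and Hey1 by 1.12 ± 0.22 (adjusted p = 0.00114). Of 12 Notch pathway genes 7 rose and 0 fell, 8 when adjusted over the list alone (list adjusted p = 0.0277).

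Six2 was 0.84 ± 0.12 higher after removal than with BIO kept (adjusted p = 0.000104), at a signal of 870 against 487. That difference was smaller than its fall over the second day with BIO kept, so Six2 stayed below its level after 24 h of BIO. Cited1 was below background on both sides (adjusted p = 0.773). Gdnf fell by 3.62 ± 0.39 (adjusted p = 3.63e-06) and Spock2 by 3.49 ± 0.31 (adjusted p = 5.14e-07), Osr1 rose at least 1.86-fold (adjusted p = 0.00253) and Meox2 at least 1.74-fold (adjusted p = 3.68e-06), in a progenitor list with 5 rises and 6 falls of 18, 5 and 7 when adjusted over the list alone (list adjusted p = 0.887). Foxc2 gained 5.26 ± 0.29 (adjusted p = 2.54e-09) and Ptpro 2.89 ± 0.32 (adjusted p = 5.68e-06), and Clic5 rose at least 8.16-fold (adjusted p = 7.47e-05). Of 8 podocyte genes 5 rose and 0 fell, 5 when adjusted over the list alone (list adjusted p = 0.00287).

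Ms4a2 and Ldlrad4, both below background in aggregates after 24 h of BIO, were at least 44.9-fold (adjusted p = 4.53e-08) and 7.73-fold higher (adjusted p = 0.000134). Slc26a7 rose at least 63.6-fold (adjusted p = 4.21e-10), the protocadherin gene Pcdh8 at least 28.4-fold (adjusted p = 4.21e-07), Kif26a at least 7.07-fold (adjusted p = 8.98e-08), Slc16a7 at least 4.51-fold (adjusted p = 7.82e-06) and Brinp1 at least 3.82-fold (adjusted p = 1.79e-05). Part of the difference in Pcdh8 lay in its fall with BIO kept on. Pmp22 rose by 5.33 ± 0.16 (adjusted p = 3.64e-12). Tagln was 3.55 ± 0.31 higher (adjusted p = 4.05e-07) and Thbs1 3.54 ± 0.22 (adjusted p = 1.01e-08). Of 15 contractile genes 14 rose and 0 fell, 14 when adjusted over the list alone (list adjusted p = 0.000689). Pdgfrb was 3.31 ± 0.24 higher (adjusted p = 6.09e-08) and Col3a1 3.10 ± 0.10 (adjusted p = 5.65e-12). Of 14 stromal genes 10 rose and 1 fell, the same when adjusted over the list alone (list adjusted p = 0.000689).

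Cell cycle genes were higher after removal, Birc5 by 1.60 ± 0.21 (adjusted p = 3.5e-05), Ccnb2 by 1.46 ± 0.16 (adjusted p = 3.36e-06) and Ccna2 by 1.39 ± 0.12 (adjusted p = 3.61e-07). Of 21 genes in the list 15 were higher and 0 lower, 16 and 1 when adjusted over the list alone (list adjusted p = 0.0215). Set against aggregates after 24 h of BIO, 0 of them rose and 2 fell over the second day without BIO, at a median of -0.061. With BIO kept on 17 fell, at a median of -0.996, so the difference lay mostly in that fall. The inhibitor gene Cdkn1a fell by 1.13 ± 0.11 (adjusted p = 1.87e-06). Sterol synthesis genes rose 5 and fell 2 of 14, 6 and 2 when adjusted over the list alone (adjusted p = 0.221 with an estimated correlation). Prrx1 was 2.21 ± 0.15 lower (adjusted p = 1.76e-08) and Snai2 1.59 ± 0.15 higher (adjusted p = 6.59e-07), among 5 rises and 3 falls of 12 mesenchymal genes, 5 and 4 when adjusted over the list alone (list adjusted p = 0.311). Part of the difference in Prrx1 lay in its rise with BIO kept on. Cdh1, the epithelial cadherin, rose by 2.23 ± 0.60 (adjusted p = 0.0132, lost when some single arrays were left out) and Cdh3 fell by 2.85 ± 0.46 (adjusted p = 0.000245). They belong to the 16 epithelial junction and keratin genes, of which 1 rose and 6 fell, 1 and 7 when adjusted over the list alone (list adjusted p = 0.471). Etv4 and Etv5, which answer to FGF, fell by 2.23 ± 0.20 (adjusted p = 5.59e-07) and 1.83 ± 0.12 (adjusted p = 1.38e-08). Cyp1b1 rose by 1.68 ± 0.12 (adjusted p = 2.63e-08). Tek fell by 2.46 ± 0.34 (adjusted p = 5.06e-05).

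Both 48 h groups were also set against aggregates after 24 h of BIO, and these comparisons carry time in culture along with BIO. With BIO kept on, Wnt targets went on rising while progenitor and cell cycle genes fell. Of 18193 genes 3792 changed, 1464 higher and 2328 lower, 1266 at least 2-fold (559 higher, 707 lower). With the 3' beta-actin control as a covariate 1516 changed (832 higher, 684 lower), 1322 of them shared, and with the Gapdh ratio 1180 (651 higher, 529 lower).

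C1qtnf3 rose by 6.31 ± 0.29 (adjusted p = 1.45e-09), with the glycogen phosphorylase gene Pygl at 5.74 ± 0.24 (adjusted p = 1.13e-09), Prss56 at least 19.7-fold (adjusted p = 2.49e-05), Krt33a at least 9.87-fold (adjusted p = 8.02e-06) and Cxcl5 at least 3.65-fold (adjusted p = 1.86e-05). Wif1 gained a further 4.24 ± 0.40 (adjusted p = 1.46e-06) and Apcdd1 2.10 ± 0.19 (adjusted p = 1.16e-06). Of 19 Wnt targets 6 rose and 0 fell, 9 when adjusted over the list alone (list adjusted p = 0.0026). The claudin gene Cldn7 rose at least 14.0-fold (adjusted p = 1.86e-05) and Ocln by 2.56 ± 0.39 (adjusted p = 0.000162), in a junction list with 6 rises and 0 falls of 16, 8 when adjusted over the list alone (adjusted p = 0.177 with an estimated correlation). Irx3 rose by 2.46 ± 0.21 (adjusted p = 4.36e-07), Papss2 by 3.17 ± 0.29 (adjusted p = 1.02e-06), and Prrx1 by 1.76 ± 0.15 (adjusted p = 3.85e-07) in a mesenchymal list with 3 rises and 1 fall of 12, 4 and 2 when adjusted over the list alone (adjusted p = 0.177 with an estimated correlation).

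Six2 fell by a further 1.88 ± 0.12 (adjusted p = 5.43e-08), Rspo1 by 1.95 ± 0.15 (adjusted p = 2.45e-07) and Itga8 by 1.70 ± 0.12 (adjusted p = 6.14e-08). Of 18 progenitor genes 7 fell and 0 rose, 7 when adjusted over the list alone (list adjusted p = 0.0218). Birc5 fell by 2.09 ± 0.21 (adjusted p = 3.04e-06) and Bub1 by 1.65 ± 0.17 (adjusted p = 4.44e-06). Of 21 cell cycle genes 17 fell and 0 rose, 17 when adjusted over the list alone (list adjusted p = 0.0327). With the beta-actin covariate 11 of them fell, at a median of -0.767 against -0.996. Plcd4 fell at least 6.60-fold (adjusted p = 2.45e-07), Pcdh8 at least 6.13-fold (adjusted p = 4.59e-05), Olfm4 at least 4.08-fold (adjusted p = 2.03e-07), Inka2 at least 3.82-fold (adjusted p = 8.13e-07) and Vcam1 at least 2.37-fold (adjusted p = 7.59e-06). Sterol synthesis genes rose 3 and fell 1 of 14, contractile genes 5 and 1 of 15, and p53 targets 0 and 4 of 10, which were 3 and 1, 6 and 1, and 0 and 7 when adjusted over the list alone (adjusted p = 0.129, 0.449 and 0.22 with an estimated correlation).

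With BIO replaced by DMSO on the second day, contractile, stromal and podocyte genes rose and Wnt targets fell. Of 18193 genes 4521 changed, 1575 higher and 2946 lower, 1527 at least 2-fold (712 higher, 815 lower). Without quantile normalization 1981 were higher and 1783 lower, the median over all genes moving by 0.12. With the 3' beta-actin control as a covariate 850 changed (564 higher, 286 lower), 743 of them shared.

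Inhba, below background after 24 h of BIO, rose at least 56.3-fold (adjusted p = 1.98e-10), Ms4a2 at least 44.9-fold (adjusted p = 1.56e-07), the calmodulin partner Pcp4 at least 20.1-fold (adjusted p = 6.26e-09), Kif26a at least 7.07-fold (adjusted p = 3.55e-08), and Slc26a7 by 5.69 ± 0.32 (adjusted p = 4.26e-09). Tagln rose by 4.58 ± 0.31 (adjusted p = 3.03e-08), with all 15 contractile genes rising, 15 when adjusted over the list alone (list adjusted p = 0.000619). Pdgfrb rose by 2.89 ± 0.24 (adjusted p = 3.32e-07) and Col1a2 by 2.74 ± 0.20 (adjusted p = 7.36e-08). Of 14 stromal genes 8 rose and 1 fell, 8 and 2 when adjusted over the list alone (list adjusted p = 0.00275). Fn1 rose by 1.63 ± 0.10 (adjusted p = 1.65e-08). Of 12 mesenchymal genes 7 rose and 1 fell, the same when adjusted over the list alone (list adjusted p = 0.0129). Foxc2 rose by 3.22 ± 0.29 (adjusted p = 6.6e-07). Of 8 podocyte genes 5 rose and 0 fell, 5 when adjusted over the list alone (list adjusted p = 0.00481). Cdh1 rose by 4.23 ± 0.60 (adjusted p = 7.87e-05).

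Lhx1 rose by 2.49 ± 0.32 (adjusted p = 2.98e-05) and Emx2 by 2.54 ± 0.27 (adjusted p = 3.68e-06). Of 18 pretubular genes 9 rose and 3 fell, 9 and 4 when adjusted over the list alone (adjusted p = 0.0705 with an estimated correlation). Notch1 rose by 1.25 ± 0.12 (adjusted p = 1.72e-06). Of 12 Notch pathway genes 7 rose and 1 fell, 8 and 1 when adjusted over the list alone (adjusted p = 0.0733 with an estimated correlation). Cxcr4 fell at least 42.1-fold (adjusted p = 4.09e-06), Fgf20 at least 6.18-fold (adjusted p = 1.19e-08) and Zmynd12 at least 2.17-fold (adjusted p = 3.59e-05). Sp5 fell by 5.26 ± 0.46 (adjusted p = 4.97e-07), Notum by 4.63 ± 0.19 (adjusted p = 1.23e-10) and Axin2 by 2.49 ± 0.17 (adjusted p = 2.95e-08). Of 19 Wnt targets 10 fell and 3 rose, the same when adjusted over the list alone (list adjusted p = 0.0132). Gdnf fell by 4.35 ± 0.39 (adjusted p = 6.03e-07) and Crym by 3.13 ± 0.15 (adjusted p = 5.8e-10). Of 18 progenitor genes 9 fell and 1 rose, 11 and 2 when adjusted over the list alone (list adjusted p = 0.0101).

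Of 14 sterol synthesis genes 10 rose and 0 fell, 11 and 1 when adjusted over the list alone (list adjusted p = 0.00481), Nsdhl by 0.68 ± 0.08 (adjusted p = 8.92e-06), and with the beta-actin covariate 1 did, at a list median of 0.42 against 0.46. BMP and TGF-beta feedback genes rose 5 and fell 1 of 11, 6 and 1 when adjusted over the list alone (list adjusted p = 0.0132), Id4 by 1.87 ± 0.11 (adjusted p = 4.6e-09). The p53 targets rose 0 and fell 6 of 10, loop and distal tubule genes 3 and 0 of 10, and glycolysis and hypoxia genes 4 and 2 of 15, which were 0 and 7, 3 and 0, and 6 and 2 when adjusted over the list alone (adjusted p = 0.0992, 0.276 and 0.0959 with an estimated correlation). With the beta-actin covariate the changes of Cxcr4, Zmynd12 and Nsdhl no longer passed. Rises with it numbered 13 of 15 contractile, 8 of 14 stromal, 6 of 18 pretubular, 2 of 12 mesenchymal, 2 of 8 podocyte, 3 of 12 Notch pathway and 1 of 11 BMP and TGF-beta feedback genes. The medians of these lists went from 2.25 to 2.58, 1.16 to 1.44, 0.48 to 1.03, 0.71 to 0.50, 1.04 to 1.18, 0.73 to 1.05 and 0.22 to 0.21. Falls numbered 5 of 19 Wnt targets and 5 of 18 progenitor genes, with medians from -0.70 to -0.81 and -0.73 to -0.48.

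**Figure D4:**
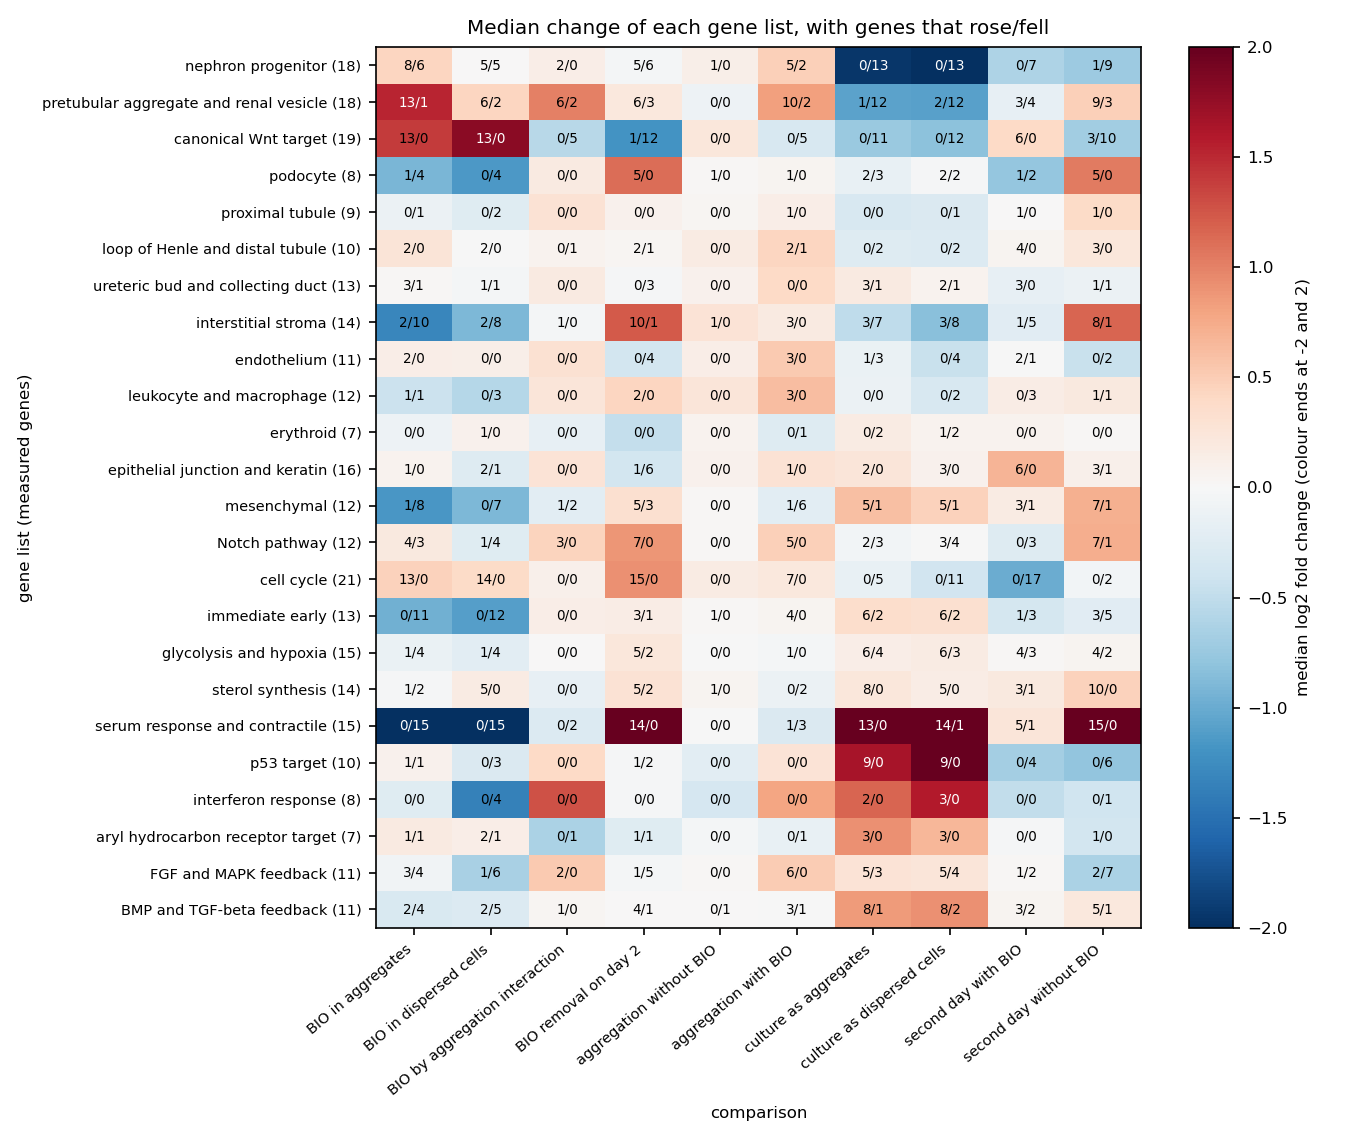
Median change of each of the 24 gene lists in the 10 comparisons, with the numbers of genes that rose and fell.

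Culture itself remade the cells, and cells from 24 h of DMSO culture were set against freshly sorted ones. Time, serum medium and the dish came together in this comparison. Progenitor and Wnt target genes fell, while genes of contraction and p53 targets rose. As aggregates 5990 of 18193 genes changed, 3350 higher and 2640 lower, 2116 at least 2-fold (1255 higher, 861 lower), and with each array centred on its median 4244 were higher and 1905 lower. With the Gapdh ratio as a covariate 3519 changed, 1699 higher and 1820 lower. As dispersed cells 6048 changed, 2722 higher and 3326 lower, 2224 at least 2-fold (1158 higher, 1066 lower). Without quantile normalization 2943 were higher and 2867 lower, and with centring 2880 and 2794.

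In aggregates Ptgs2 rose at least 76.4-fold (adjusted p = 1.22e-12), Ms4a2 at least 108-fold (adjusted p = 2.35e-08), the potassium channel gene Kcna1 at least 56.2-fold (adjusted p = 1.25e-09), the galectin gene Lgals3 at least 38.0-fold (adjusted p = 3.71e-09), Inhba at least 26.6-fold (adjusted p = 4.11e-10) and Fgf5 at least 20.04-fold (adjusted p = 5.5e-07). Cryab, a small heat shock protein gene, rose by 7.42 ± 0.51 (adjusted p = 1.5e-08), Tagln by 6.82 ± 0.31 (adjusted p = 1.78e-10) and Ccn2 by 5.86 ± 0.11 (adjusted p = 1.11e-14). Of 15 contractile genes 13 rose and 0 fell, 14 when adjusted over the list alone (list adjusted p = 0.00448). Perp rose by 3.07 ± 0.23 (adjusted p = 3.01e-08) and Cdkn1a by 2.72 ± 0.11 (adjusted p = 7.29e-11). Of 10 p53 targets 9 rose and 0 fell, 9 when adjusted over the list alone (list adjusted p = 0.0209). BMP and TGF-beta feedback genes rose 8 and fell 1 of 11, the same when adjusted over the list alone (list adjusted p = 0.0209).

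Lhx1 fell at least 6.72-fold from a signal of 287 in fresh cells (adjusted p = 6.58e-10), with Mfap4 at least 20.2-fold (adjusted p = 8.19e-11), Cldn11 at least 15.5-fold (adjusted p = 2.12e-08), the retinoid binding gene Crabp2 at least 14.7-fold (adjusted p = 2.04e-07), Dleu7 at least 7.58-fold (adjusted p = 1.02e-05), Galnt5 at least 7.24-fold (adjusted p = 1.33e-09), Ppp1r14a at least 4.25-fold (adjusted p = 1.47e-05) and Svopl at least 2.73-fold (adjusted p = 2.09e-10). Cited1 fell at least 3.26-fold (adjusted p = 1.75e-05), Gdnf by 2.84 ± 0.39 (adjusted p = 2.87e-05) and Rspo1 by 2.62 ± 0.15 (adjusted p = 2.19e-09). Of 18 progenitor genes 13 fell and 0 rose, 13 when adjusted over the list alone (list adjusted p = 0.000434). Pretubular genes fell in 12 of 18 and rose in 1, 12 and 2 when adjusted over the list alone (list adjusted p = 0.0307). Tnfrsf19 fell by 3.76 ± 0.17 (adjusted p = 1.23e-10) and Axin2 by 1.70 ± 0.17 (adjusted p = 8.69e-07). Of 19 Wnt targets 11 fell and 0 rose, 11 and 2 when adjusted over the list alone (list adjusted p = 0.00448). Stromal genes rose 3 and fell 7 of 14, mesenchymal genes 5 and 1 of 12, cell cycle genes 0 and 5 of 21, sterol genes 8 and 0 of 14, and aryl hydrocarbon receptor targets 3 and 0 of 7, the same when adjusted over the list alone but for 9 sterol genes (adjusted p = 0.0559, 0.0559, 0.356, 0.115 and 0.0621 with an estimated correlation).

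In dispersed cells Ptgs2 rose at least 85.8-fold (adjusted p = 7.05e-13), Lgals3 at least 49.95-fold (adjusted p = 1.82e-09), Inhba at least 44.7-fold (adjusted p = 9.96e-11), Fgf5 at least 35.4-fold (adjusted p = 1.24e-07) and Cryab by 7.57 ± 0.51 (adjusted p = 9.7e-09). Mfap4 fell at least 20.2-fold (adjusted p = 1.96e-11), Crabp2 at least 14.7-fold (adjusted p = 6.59e-08), Dleu7 at least 7.58-fold (adjusted p = 1.44e-06), Lhx1 at least 6.72-fold (adjusted p = 7.64e-10) and Sp5 at least 6.41-fold (adjusted p = 1.3e-07). Crym fell by 3.31 ± 0.15 (adjusted p = 1.18e-10). Contractile genes rose 14 and fell 1 of 15 (list adjusted p = 0.00455), p53 targets 9 and 0 of 10 (list adjusted p = 0.00871), BMP and TGF-beta feedback genes 8 and 2 of 11 (list adjusted p = 0.00871), mesenchymal genes 5 and 1 of 12 (list adjusted p = 0.04), progenitor genes 0 and 13 of 18 (list adjusted p = 0.000825) and Wnt targets 0 and 12 of 19 (list adjusted p = 0.00469). When adjusted over the list alone these were 14 and 1, 10 and 0, 8 and 2, 5 and 1, 0 and 14, and 1 and 12. Pretubular genes rose 2 and fell 12 of 18, interferon genes 3 and 0 of 8, stromal genes 3 and 8 of 14, cell cycle genes 0 and 11 of 21, sterol genes 5 and 0 of 14 and aryl hydrocarbon receptor targets 3 and 0 of 7 (adjusted p = 0.0769, 0.423, 0.0899, 0.194, 0.194 and 0.0919 with an estimated correlation). When adjusted over the list alone these 6 lists had 2 and 12, 4 and 0, 3 and 9, 0 and 12, 6 and 0, and 3 and 0. Without dispersed DMSO replicate 3, apart in Ifit1 at 10.3 against 6.79 and 6.67, 2 interferon genes rose.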

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

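The tests of explanations in this part were chosen only after the results were seen, while the splits of the arrays were planned before.

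The first group of results stands here because the response to BIO differed between aggregates and dispersed cells in a test of the difference itself. By log2 estimate the positive interactions were led by Lhx1 5.44, Lhx1os 4.43, Plcd4 3.67, Lama4 3.58 and Morn5 3.11, and the negative ones by Serpina9 -3.62, Wif1 -3.49, Dcc -3.34, Tenm2 -3.30 and Lrrc20 -3.21. Among listed genes, Papss2 2.72, Hey1 2.26, Pdgfrb 2.16, Heyl 1.98, Itga8 1.74, Hes1 1.27, Uncx 1.13, Spry2 0.99, Id4 0.69, Ncam1 0.62 and Spry1 0.59 were higher in aggregates. Irx3 -1.58, Dact1 -1.54, Prrx1 -1.36, Apcdd1 -1.29, Tnfrsf19 -1.07, Ccn2 -0.82, Cyp1b1 -0.82, Cdh11 -0.61 and Acta2 -0.57 were lower, though Acta2 turned to 0.064 with the mean of its probe sets and 0 contractile genes passed with the beta-actin covariate. All 4 groups were below background for Morn5 and Serpina9, 3 of them for Lhx1, Lhx1os and Plcd4, and some for Wif1, Dcc, Tenm2 and Lrrc20, so these sizes are not exact.

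A signal also appeared in probe sets that the comparisons did not use, those without a single gene symbol. Of 10092 such probe sets 598 changed with BIO in aggregates, 348 higher and 250 lower. Among those above background on average, the largest rise was 3.29 ± 0.19 (limma adjusted p = 2.28e-08), the next came up from below background (adjusted p = 0.0482), and the largest falls both ended below background (adjusted p = 9.41e-07 and 1.45e-05).

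The pretubular genes and Lhx1 gained more from BIO in aggregates. Weaker activation of the pathway in dispersed cells is argued against, since the canonical Wnt targets had a median interaction of -0.56 (p = 1.62e-05 with an estimated correlation), the opposite direction. For Lhx1 the interaction with the beta-actin control as a covariate was 4.89 ± 0.55 (adjusted p = 0.000935) beside 5.44. This does not test a loss of signal, since a loss in the aggregated BIO arrays would lower Lhx1 there and not raise it. For the list as a whole an effect that follows the control cannot be told apart from a real difference, since the median interaction went from 1.01 to 0.44 and all 3 aggregated BIO arrays were low in the control. Signalling through Notch between touching cells stays open, with a median interaction of 0.11 for the 7 pathway genes outside the list (p = 0.331 with an estimated correlation).

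The 5 largest falls with aggregation under BIO, Malat1, Gdap10, Srrm2, Nfix and Taok3, followed the 3' beta-actin control on single arrays at r = 0.927 (permutation p = 0.00069, Spearman 0.97), and at 0.902 without the arrays farthest out, aggregated BIO replicate 3 and BIO 48 h replicate 1. A lower level of the whole transcripts stays open, since of the 8 other probe sets of Malat1 and Srrm2 above background in dispersed BIO 5 fell less by more than 2 combined SE (0.120 to 0.260 of the fall) and 3 fell about as much. The 5 were above background in both groups, while the 3 ended below it in aggregated BIO, so the sizes of their falls are not exact. For Gdap10, Nfix and Taok3 the probe sets used ended below background and had 4 others above background on average, 0 of these for Gdap10. Those of Taok3 changed by 0.40 ± 0.23 and -0.43 ± 0.32 and so did not share its fall, though 1 more Taok3 probe set, below background on average, fell past the threshold. Those of Nfix changed by -0.50 ± 0.50 and -3.15 ± 0.38. A lower level of the whole transcripts was thus not settled for these genes either. A 3' bias of the amplified RNA is not settled either, since with the Gapdh 3' over 5' ratio as a covariate the genes kept a median share of 0.765 of their falls (0.748 to 0.972), while the beta-actin 3' over 5' ratio was 17.1 ± 2.1 (SD, n = 3) in aggregated BIO against 11.04 ± 0.46 in dispersed BIO. Of 18193 genes 115 followed the control (85 rising and 30 falling with it), and a loss of signal could not be separated from a real change along with beta-actin, as all 3 aggregated BIO arrays were low in it (2669 to 5410).

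Interstitial stroma genes fell with BIO in both formats. Fewer stromal cells among those sorted on Six2-driven GFP stay open. Past the threshold 4 rises stood beside 18 falls, Penk in both formats, Alx1 in aggregates, from below background, and Meis1 in dispersed cells, too few to decide. In dispersed cells the list median was -0.84 with the beta-actin control as a covariate and -0.91 without. The control read 8628 to 9219 in dispersed BIO and 11990 to 12310 in dispersed DMSO. It was thus tied to these groups too, so the small shift does not decide on a loss of signal. A lower level of stromal genes in the progenitors themselves stays open as well and was not tested.

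The arrays were also regrouped and the calls counted again. In each of the 9 comparisons of 3 with 3 arrays the real grouping was the 1 of 10 splits with the most, and so few splits cannot give a share under 0.05. The real and the highest other counts were 5455 and 29 for BIO in aggregates, 5230 and 2 for BIO in dispersed cells, 3711 and 3 for removal, 477 and 1 for aggregation in DMSO and 3135 and 2 in BIO. They were 5990 and 3 for culture as aggregates, 6048 and 1 as dispersed cells, 3792 and 8 for the second day with BIO and 4521 and 2 without. For the interaction 9 of 100 splits, the real one included, gave as many calls as the real 285, with a highest of 1586, so chance was not excluded. The 8 others all kept the arrays of one treatment apart by format and so hold real differences, and the splits that mixed both treatments gave at most 2.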

How the results depend on the processing

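The settings with 4 arrays left out or with a covariate were chosen after the data were seen, the others before. Among counts of genes, 100 of 140 values under whole settings stayed within 1.5 times the reported count and 40 moved. The correlation of the BIO responses moved as well, to 0.895 over the brighter genes. Unless a reason is given, the cause was not tested.

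As deposited, aggregation in DMSO gave 272 genes and in BIO 2059, and centring gave 922 for the former. Only brighter genes gave 859 for aggregation in DMSO. The mean of all probe sets gave 150 for the interaction. Every probe set, a larger number of tests, gave 8255 for BIO in aggregates, 903 and 5641 for aggregation in DMSO and BIO, 10277 and 9496 for culture as aggregates and dispersed cells, and 6057 and 7980 for the second day with and without BIO. Only the arrays compared, which leave 4 residual degrees of freedom, gave 1820 for removal, 6 and 2040 for aggregation in DMSO and BIO, and 1708 and 2559 for the second day with and without BIO. Array weights gave 545 for the interaction and 829 for aggregation in DMSO, and a trend with a robust prior gave 735 for the latter.

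A 2-fold minimum, which removes small changes by construction, gave 1950 and 1898 for BIO in aggregates and dispersed cells, 163 for the interaction, 1452 for removal, and 109 and 636 for aggregation in DMSO and BIO. It gave 2116 and 2224 for culture as aggregates and dispersed cells, and 1266 and 1527 for the second day with and without BIO.

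Without 4 arrays aggregation in DMSO gave 277. The Gapdh covariate gave 226 and 1087 for aggregation in DMSO and BIO, 3519 for culture as aggregates and 1180 for the second day with BIO. The beta-actin covariate gave 2405 for BIO in aggregates, 120 for the interaction, 358 for aggregation in BIO, and 1516 and 850 for the second day with and without BIO.

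Leaving out 1 array gave 4616 to 5007 genes for BIO in aggregates, 4337 to 4480 for BIO in dispersed cells, 171 to 277 for the interaction, 2984 to 3441 for removal. It gave 138 to 306 and 1907 to 2673 for aggregation in DMSO and BIO, 4936 to 5454 and 5165 to 5385 for culture as aggregates and dispersed cells, and 2946 to 3527 and 3594 to 4089 for the second day with and without BIO.

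Of 737 calls for named genes, 44 were lost as deposited, 23 when centred, 99 with the mean of probe sets, 19 with every probe set, 139 with only the arrays compared, 18 with weights, and 5 with the trend. Another 1 was lost with log2(value + 16), 173 with the 2-fold minimum, 144 when any 1 array was left out, 78 without 4 arrays, 142 with the Gapdh and 195 with the beta-actin covariate. The filter on dim genes lost 0 of the 447 calls in the genes it kept, with fewer tests to adjust for. The other calls were in dimmer genes that it removed, so it does not speak to them. Directions reversed with the mean of probe sets for Cdkn1a (-0.51 with BIO in aggregates, 0.056 on the second day without BIO), Acta2 (0.064, interaction), Pfkp (-0.32, removal), Tyms and Etv4 (-0.57 and -0.085, aggregation in BIO), Podxl (0.059, culture as aggregates) and Fdft1 (-0.11, culture as dispersed cells). They reversed with the Gapdh covariate for Esam (0.23, second day with BIO), and with the beta-actin covariate for Taok3, Osr1 and Cdh2 (0.061, 0.46 and 0.079, aggregation in BIO) and Lrp2 (-0.30, second day without BIO).

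Replicate numbers did not pair the arrays. Same-numbered arrays of compared groups deviated together at r between -0.388 and 0.196, and 2 of 21 arrays correlated best with their own number. With the replicate number as a block the counts were 5250 and 4982 for BIO in aggregates and dispersed cells, 244 for the interaction, and 3532 for removal. They were 319 and 2764 for aggregation in DMSO and BIO, 5756 and 5880 for culture, and 3576 and 4303 for the second day, with 21 named calls past the threshold lost. Signal over background limits the folds that can be given, with 76.0 to 79.6% of genes on each array above it.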

Other observations

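The tests in this part were chosen only after the results were seen. Culture changed genes beyond the programmes described. In aggregates the immediate early genes Ier3 and Atf3 rose by 4.15 ± 0.26 (limma adjusted p = 4.71e-09) and 3.88 ± 0.22 (adjusted p = 1.74e-09), while Fosb fell by 2.11 ± 0.22 (adjusted p = 1.74e-06). The keratin gene Krt19 rose by 3.76 ± 0.27 (adjusted p = 2.3e-08), Prrx1 by 2.32 ± 0.15 (adjusted p = 4.82e-09) and Id1 by 1.67 ± 0.20 (adjusted p = 7.72e-06). Glycolysis genes split, Pfkp rising by 1.97 ± 0.16 (adjusted p = 9.78e-08) and Pfkl falling by 2.19 ± 0.25 (adjusted p = 4.33e-06). Bmp7 fell by 2.40 ± 0.13 (adjusted p = 1.24e-09) and Ramp2 by 2.91 ± 0.16 (adjusted p = 8.05e-10).

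The effects of BIO and of its removal can be set side by side, as they share no arrays. Of 3701 genes that BIO changed the same way in both formats, 1413 changed the opposite way on removal and 274 the same way. Over all genes the changes correlated at r = -0.375 (Spearman -0.255), and at -0.48 over the brighter genes. On removal Adm rose by 2.25 ± 0.25 (adjusted p = 6.12e-06), Bmp7 fell by 1.66 ± 0.13 (adjusted p = 1.7e-07) and Ramp2 by 1.64 ± 0.16 (adjusted p = 9.9e-07).

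BIO belongs to the indirubins, a family with ligands of the aryl hydrocarbon receptor, so its targets were examined. Activation after 24 h was not decided. Cyp1b1, a direct target, fell by 2.53 ± 0.12 with BIO in aggregates and fell by 1.71 ± 0.12 in dispersed cells (adjusted p = 1.53e-10 and 9.73e-09). Cyp1b1 rose by 3.17 ± 0.12 during DMSO culture as aggregates (adjusted p = 1.56e-11) and was 1.68 ± 0.12 higher on removal of BIO (adjusted p = 2.63e-08). Tiparp rose by 0.30 ± 0.06 with BIO in aggregates (adjusted p = 0.00158), a call lost with the beta-actin covariate, with the mean of its probe sets and with only the arrays compared. In dispersed cells Ahrr rose by 0.92 ± 0.25 and Nqo1 by 0.64 ± 0.22 with BIO (adjusted p = 0.0117 and 0.0377), calls lost with the Gapdh covariate, and neither passed in aggregates (adjusted p = 0.649 and 0.605).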
